A study of Macaca mulatta with 2 samples.

How the data were processed

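Primary Sertoli cell cultures, made from the testes of rhesus macaques (Macaca mulatta), were profiled on 2 two-colour Agilent microarrays. Sertoli cells are the somatic cells of the seminiferous tubule that nurse the germ cells. The infant cultures came from males under 3 months old. The pubertal cultures came from males of 18 to 22 months in which puberty had been brought on with gonadotropin-releasing hormone (GnRH) at 0.15 µg/min, in pulses of 2 min set 3 h apart, for 4 to 5 weeks. All cultures received 100 nM testosterone and 5 ng/ml follicle-stimulating hormone (FSH) for 24 h, per the labels' protocols. Each array set 1 pubertal culture against 1 infant culture from different animals, and the dyes were swapped: on array 1 the pubertal RNA was in Cy5 and the infant RNA in Cy3, and on array 2 the other way round, per the labels. The 2 arrays were read from 1 slide in 1 scan, so no slide or scan batch could be tested.

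The arrays carried 60-base probes of a human whole-genome design (014850), whose coordinates are on the human build hg17, per the file headers. Macaque RNA was thus measured with human probes. No macaque genome was used here to look for mismatched probes, which bind less of both RNAs of a pair. The scanner software was Agilent Feature Extraction 9.5.1.1, per the submitters' processing notes. The deposited scanner files give the mean spot intensity and the median local background intensity of each channel, not normalized. They also give processed intensities, background-subtracted and dye-normalized by the scanner software, and a log10 ratio of Cy5 over Cy3 made from them, per the file headers. Flags for each spot, a unit of their own in the deposited files, mark signals well above background, saturated spots and outliers. The authors' deposited table holds log2 ratios for 4848 probes in 1 column per array. Set against the scanner's log ratios, its columns had slopes of 1.006 and 1.003 on the log2 scale in the pubertal-over-infant direction, and its values differed from those ratios by medians of -0.0159 and -0.000425. All 4848 probes had a size of at least 1 in 1 or both columns. The normalization behind the table and the reason for its empty cells (342 and 355) are not given in the sources used here.

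From the scanner files, mean intensities were corrected with their local backgrounds by normexp (offset 50) in limma 3.58.1 under R 4.3.3, and each array was normalized by loess. The offset adds 50 to the corrected intensity of both channels, which makes the ratios of dim probes smaller. Sizes, ranks and counts by fold given for dim genes depend on it. Control spots had no weight in the loess, spots with outlier flags were left out, and saturated spots were kept. Spots of 1 probe were averaged, which gave 41000 probes from 43376 spots. Log2 ratios were turned to pubertal over infant by the dye labels. Probes were kept where the spot was well above background in the pubertal channel of both arrays, or in the infant channel of both, and 15232 probes were left out. Of several probes of a gene, the one with the highest mean intensity stood for it. Probes without a gene symbol stayed as single probes. This left 20227 genes, 12240 of them with a symbol. Of these symbols 10147 stood in the macaque gene tables used here and 326 were updated through a synonym to match lists. Genes keep the name given in the files, so that CDC2 stands for CDK1, MLLT4 for AFDN and SC5DL for SC5D.

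Differences were tested with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) on the 2 turned ratios, which leaves 1 residual degree of freedom beside 3.98 from the prior. A dye term would have left none. Errors are the moderated standard errors (SE) of that fit, with n = 2 array pairs. Beside the test, genes at least 2-fold apart in the same direction on both arrays were counted. The same count was made for Cy5 over Cy3, where a difference between ages cancels and a dye effect does not. Differences between the cultures of the 2 pairs, which came from different animals, do not cancel there either. The count thus does not measure dye alone. Gene lists were tested with limma's camera (preset inter-gene correlation 0.01, two-sided, adjusted over the 24 lists). Its p treats the genes of a list as the sampled units, so it does not measure the spread between animals. With an estimated correlation that test rests on the 1 residual degree of freedom, so a list that misses the threshold there decides little. The lists covered Sertoli cell identity, the immature Sertoli cell, the mature Sertoli cell, FSH receptor, cAMP and PKA signalling, cAMP-induced genes, androgen target genes, the blood-testis barrier and cell junctions, Sertoli growth factors for germ cells, retinoic acid metabolism and signalling, glucose uptake, glycolysis and lactate export, cell division, cholesterol synthesis and uptake, steroidogenesis and the Leydig cell, peritubular myoid and smooth muscle, fibroblast and interstitial stroma, germ cell, macrophage and leukocyte, endothelial cell, erythroid cell, extracellular matrix and basement membrane, WNT and Notch signalling, interferon response, stress, heat shock and hypoxia, and ribosomal proteins. Where the text places a list among random lists, these were 10000 lists of the same size matched on mean intensity in 20 bins.

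The lists, the tests, the named-gene rule and the main alternatives were fixed before the data were examined. The rule named FSHR, then the 12 genes per direction with the largest mean log2 ratio among genes past the test. Where fewer passed, the places went to the genes of the same sign on both arrays with the largest smaller-of-the-2-arrays ratio, given as values and not as calls. It left out names that are not gene symbols and genes with outlier-flagged spots. It also took up to 4 members with the smallest p of each list. Of the genes the rule picked, 3 are not reported here and are not among the named genes counted. Genes named outside the rule were chosen after their values were seen, except that the brightest members of a list were taken by intensity and further members past the test over a list alone by that test; each is marked where it is named. Alternatives tried were no background subtraction, the scanner's processed signals, a normexp offset of 0, median centring, Aquantile scaling between arrays, no filter and a stricter filter on dim probes, the mean of a gene's probes, single probes, kept outliers, each array alone, separate channels without the array as a block, an intensity trend in eBayes, list tests with an estimated correlation and with fry, and other thresholds.

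The pipeline was tested on simulated data. In 20 simulated pairs of arrays over the 20227 genes, drawn with the variance of the real fit, 200 genes were changed, 50 at each fold. The fit recovered 0.7% of the 2-fold changes, 37.3% of the 4-fold, 89.6% of the 8-fold and 97.7% of the 16-fold changes, and 9.12% of its calls were false. These rates hold for 200 changed genes and a mean of 124 calls, since the adjusted p depends on how many other genes pass. Fewer changed genes make the cut stricter, so a lone large change can be missed. When the pubertal signal of 147 real probes was multiplied by 4, the ratio rose by a median of 1.82 on the log2 scale. That it rose for 100% of them was fixed by the multiplication. Only probes well above background in Cy3 on both arrays were drawn, so dim probes were not tried. Camera called a list of 29 genes shifted by 0.5 in 20 of 20 simulated pairs, and 2 of 460 unshifted lists, in noise without correlation between genes. The precision of every value is limited by the 2 arrays.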

Results

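The data were 2 dye-swapped arrays, each comparing Sertoli cells of a GnRH-induced pubertal macaque with those of an infant, all under testosterone and FSH. The design asks how the 2 stages of Sertoli cell maturation differ in expression under the same hormones. No culture without hormones is analysed here, so the response to the hormones themselves was not measured. Of the 43376 spots on each array, 74.8% were well above background for the pubertal RNA in Cy5 and 60.9% for the infant RNA in Cy3 on array 1. On array 2, 62.6% were well above background for the pubertal RNA in Cy3 and 71.5% for the infant RNA in Cy5. Saturated spots numbered 586 and 428 in the Cy5 channels of arrays 1 and 2 and 0 and 2 in the Cy3 channels.

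CST9L, a cystatin-like gene expressed in Sertoli cells, stood furthest apart between the stages by the dye labels as given; with array 2 turned the other way its 2 values would cancel. Its log2 ratio of pubertal over infant was 4.85 on array 1 and 4.58 on array 2, a mean of 4.71 ± 0.25 (moderated SE, n = 2 array pairs) or 26.3-fold, and 5.38 or 41.6-fold with the scanner's signals. Its probe (A_23_P143365) lies on human chromosome 20 at 23493399 to 23493458 (hg17). PCDH17, a protocadherin of cell adhesion, was at 2.35 and 3.14 on the 2 arrays, and BDKRB2, the bradykinin B2 receptor, at 3.46 and 1.62. RLN3, a relaxin-family hormone, had 1.94 and 2.57, and SPATA22, a gene of meiotic recombination, 2.11 and 2.08. In the other direction RGS5, a regulator of G-protein signalling known from pericytes, was at -1.89 and -2.20, a mean of -2.05 ± 0.25. AGT, which encodes a plasma peptide precursor of blood pressure control, was at -2.20 and -1.36, and GPC3, a glypican of growth control, at -2.07 and -1.66.

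The remaining genes with the largest shared differences included the melanosome transport gene MLPH (2.55 and 1.66), the cargo receptor LMAN1 (2.05 and 1.95), GAL3ST1, a sulfotransferase of sulfoglycolipids (1.93 and 1.59), MNDA (1.81 and 1.66), MAN2B2 (1.82 and 1.48), RIPK4 (1.76 and 1.60) and the interferon-induced OAS1 (1.68 and 1.55). Lower in pubertal cells on both arrays were the steroid enzyme gene CYP17A1 (-2.12 and -1.45), the orphan receptor gene NR0B1 (-2.01 and -1.55), PTGDS, a prostaglandin D synthase (-1.68 and -1.65), STC2 (-1.61 and -1.90), TMTC1 (-1.47 and -1.61), DLK1 (-1.32 and -1.99), and 2 aldo-keto reductase genes, AKR1C1 (-1.61 and -1.46) and AKR1B10 (-1.35 and -2.68). The probes of AKR1C1 and AKR1B10 can also bind transcripts of close relatives. In the infant channel MNDA and OAS1 were well above background on 1 of 2 arrays, as was AGT in the pubertal channel. MLPH and AKR1B10 each had a saturated spot in their brighter channel on 1 array. A further kept probe gave a mean of 0.14 for RIPK4 against 1.68 for the first, and 0.43 for LMAN1 against 2.00. For RGS5 and STC2 the further probe kept the sign, at -1.83 and -1.21, as did those of TMTC1 at -1.28 and -1.08 and of MLPH.

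**Figure D1:**
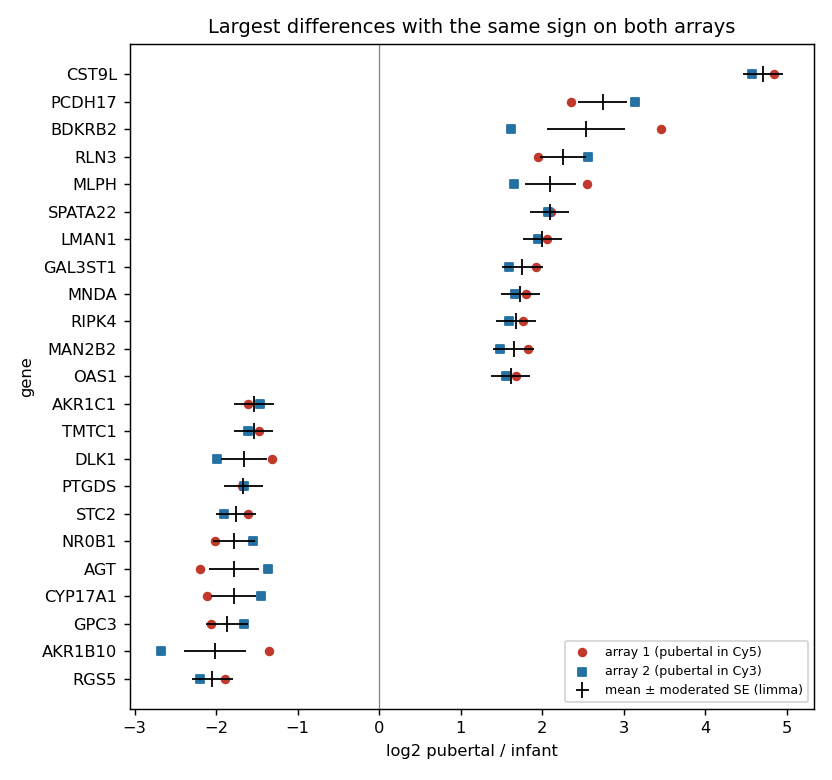
Log2 ratio of pubertal over infant (x axis) of 23 genes with the largest differences shared by both arrays (y axis), with circles for array 1, squares for array 2 and bars for the mean with its moderated SE. CST9L lies at 4.85 and 4.58, and RGS5 at -1.89 and -2.20.

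No gene passed limma's test over the 20227 genes (0 at an adjusted p under 0.05). CST9L had the lowest value (adjusted p = 0.152), and the other 22 genes above had an adjusted p of 0.907. At an unadjusted p under 0.05 there were 818 genes, 454 higher and 364 lower, where chance alone gives 1011. By size, 69 genes were at least 2-fold higher in pubertal cells on both arrays and 69 at least 2-fold lower, against 19.6 and 13.6 for independent arrays. In the Cy5 over Cy3 direction, where a difference between ages cancels, 49 genes were at least 2-fold higher and 107 lower, against 19.7 and 13.5 for independent arrays, a balance that turned with the scanner's signals (215 and 164) and with median centring (1521 and 9). Across genes, which are not independent replicates, the turned ratios had a Pearson r of -0.06 and a Spearman rho of -0.10, and 45.3% of genes had the same sign on both arrays. CST9L passed the test under 5 of the alternatives, with an adjusted p of 0.0474 under the stricter filter on dim probes, 0.0214 with the scanner's signals, 0.00335 at an offset of 0, 0.000429 with an intensity trend and 1.87e-06 with median centring. Without a filter on dim probes its adjusted p was 0.9999. Median centring left the tested genes at medians of 0.62 on array 1 and -0.41 on array 2, a shift towards Cy5 on both. The p of CST9L under median centring is thus not comparable with the others.

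**Figure D2:**
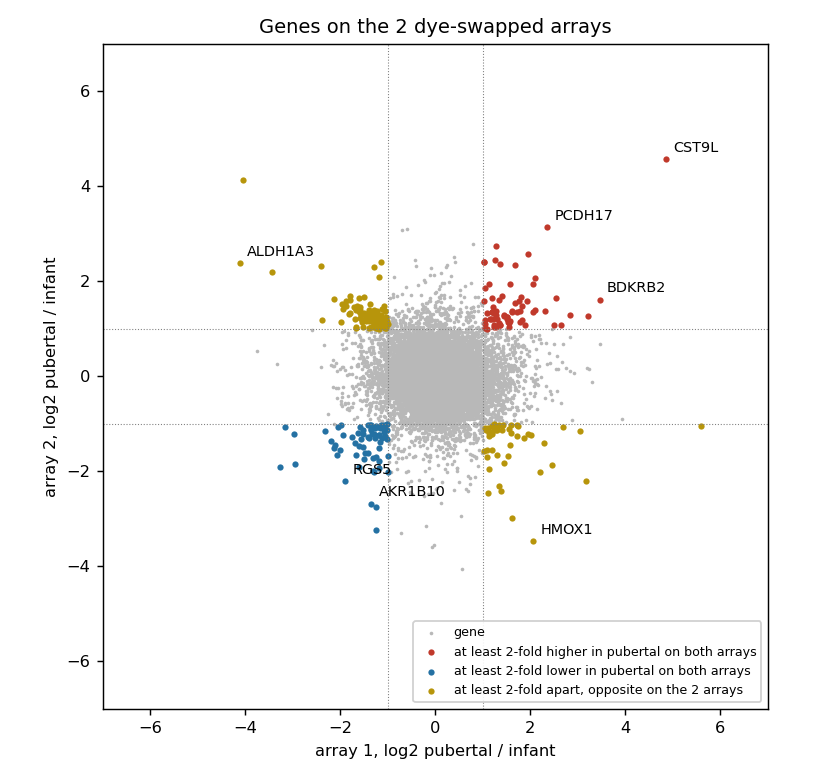
Log2 ratio of pubertal over infant of each of the 20227 genes on array 1 (x axis) and array 2 (y axis), with dotted lines at 2-fold. Red and blue points are the 69 and 69 genes at least 2-fold apart in the same direction, and ochre points the 156 genes at least 2-fold apart in opposite directions.

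FSHR, the FSH receptor, was dim, with pubertal signals well above background on 1 of 2 arrays, and its ratios of -0.24 and -0.17 (mean -0.20 ± 0.24) leave a difference between the stages undecided. Among the 44 measured genes of FSH receptor, cAMP and PKA signalling, 9 were higher and 8 lower on both arrays. The phosphodiesterase PDE4D was at 0.76 and 0.77, and the receptor kinase GRK5 at -0.58 and -0.60. Further probes of PDE4D had means of 0.32 and -0.08. ADCY3 was at 1.02 and 0.29 and CRTC3 at -0.66 and -0.39. Of 26 cAMP-induced genes 9 were higher and 2 lower on both arrays, with PER2 at 1.43 and 0.46 (mean of a further probe 0.23), PLAT at 1.60 and 0.25 and EGR1 at -0.46 and -0.93. The other 15 had opposite signs on the 2 arrays, and the list's medians were 0.48 and -0.10. Of 22 androgen target genes 9 were higher and 5 lower, with MAF at 2.39 and 0.49, ELL2 at 0.94 and 0.73 (saturated on 1 array), ACSL3 at 0.68 and 0.73 and NDRG1 at -0.93 and -1.34. Further probes had means of 0.18 for MAF and -0.18 for NDRG1. In the pubertal-over-infant direction neither these 3 lists (camera adjusted p of 0.575, 0.247 and 0.316) nor any of their genes, adjusted over the list alone, passed the test. The cAMP-induced list passed camera in the Cy5 over Cy3 direction (adjusted p = 0.0106, and 0.918 with an estimated correlation).

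The Sertoli cell lists as wholes did not pass under the main processing. Of 35 genes of Sertoli cell identity 11 were higher and 6 lower on both arrays (camera adjusted p = 0.247). Adjusted over the list alone, CST9L, CLDN11 and PTGDS passed (3 of 35). CLDN11, a claudin of Sertoli tight junctions, was at 1.45 and 1.28, and a further probe had a mean of 0.86. DMRT1, a male sex-determination factor, was at 1.24 and 0.50. Of 18 genes of the immature Sertoli cell 4 were higher and 3 lower (adjusted p = 0.666), and NR0B1 passed over the list alone. ETV5 was at -0.84 and -0.44, HSD17B1 at -0.17 and -1.51 (means of further probes 0.07, 0.22 and -0.58) and FGF9 at 1.55 and 0.17. Of 26 genes of the mature Sertoli cell 9 were higher and 4 lower (adjusted p = 0.141), with CLDN5 at 0.76 and 0.50 (mean of a further probe 0.08) and SLC16A1 at -0.89 and -0.31. CST9L and CLDN11 passed over this list alone. With median centring, which left the tested genes shifted towards Cy5, the identity and mature lists passed as higher (adjusted p of 0.00263 and 0.000187). With single probes the mature list did (adjusted p = 0.0373).

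Genes of the blood-testis barrier and cell junctions rose as a group in pubertal cells by the camera test, but stood out from random lists on array 2 only. Of 40 measured, 19 were higher and 3 lower on both arrays, and the medians were 0.10 and 0.34, at percentiles 70.4 and 100 of random lists. The camera adjusted p was 0.00367, and 0.672 with an estimated correlation. Beside CLDN11, MLLT4, an adherens junction scaffold, had a mean of 1.04 ± 0.24, and F11R, a junctional adhesion molecule, at 1.67 and 0.70, with -0.06 as the mean of a further F11R probe. Genes of cholesterol synthesis and uptake also rose by this test (adjusted p = 0.00437, and 0.672 with an estimated correlation), but their medians were -0.01 on array 1 and 0.35 on array 2. Of 30 measured, 9 were higher and 3 lower on both. INSIG1, a sterol sensor, was at 0.52 and 1.82, SQLE at 0.55 and 0.59, SC5DL at 0.71 and 0.46 and SREBF1, with saturated Cy5 spots on both arrays, at 0.31 and 1.02. No single gene of either list passed over its list alone. On the same arrays germ cell markers were higher (medians 0.58 and 0.46) and stromal markers lower (medians -1.08 and -0.31) in the pubertal cultures.

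Germ cell genes formed the group with the lowest p by the dye labels as given, and did not pass in the Cy5 over Cy3 direction (adjusted p = 0.535). Of 29 measured, 22 were higher and 1 lower in pubertal cultures on both arrays, and the medians were 0.58 and 0.46. The camera adjusted p was 1.18e-10, and 0.672 with an estimated correlation. STK31 was at 2.06 and 1.35, PRAME at 1.34 and 1.61, DAZL, an RNA-binding protein of germ cells, at 1.18 and 1.65 and FGFR3 at 1.27 and 0.92 (mean of a further probe 0.27). STK31, PRAME and DAZL passed adjusted over the list alone (3 of 29), and 0 of 29 passed over all genes. Chosen after their values were seen, the germ cell helicase gene DDX4 was at 0.61 and 0.28, the synaptonemal complex gene SYCP3 at 1.31 and 0.47 and MAEL at 1.16 and 0.50. SYCP3 was well above background for the infant RNA on 1 of 2 arrays.

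Genes of fibroblasts and the interstitial stroma fell as a group. Of 27 measured, 17 were lower and 2 higher in pubertal cultures on both arrays, with medians of -1.08 and -0.31 and a camera adjusted p of 1.99e-09 (adjusted p = 0.672 with an estimated correlation). NR2F2 was at -1.60 and -1.06, FBLN1 at -1.28 and -1.30 and COL6A3 at -1.14 and -1.04, while IGFBP3 was at 1.13 and 1.95. Further probes of FBLN1 had means of -0.49 and -0.10. Adjusted over the list alone 6 of 27 passed, the others, named for this and not by the rule, being PDGFRB (-1.08 and -1.01) and TCF21 (-1.26 and -0.79), and 0 passed over all genes. The steroidogenesis and Leydig cell list also fell by camera, but the median of its mean ratios was -0.10, at percentile 6.79 of random lists. Of 23 measured, 9 were lower and 3 higher on both arrays, the medians were -0.17 and -0.55, and the camera adjusted p was 0.000857 (adjusted p = 0.672 with an estimated correlation). Over the list alone 7 passed, all lower: CYP17A1, NR0B1, PTGDS, DLK1 and AKR1C1, and outside the rule AKR1C3 and AKR1B1. PTGDS also stands in the Sertoli cell identity list and NR0B1 in that of the immature Sertoli cell. The probe of AKR1C1 can bind transcripts of close relatives, so the 7 are not separate signs of Leydig cells. Of these CYP17A1 makes androgen precursors, and the 3 AKR genes encode reductases with wide substrates, of which AKR1B1 had a saturated infant spot on 1 array. Genes of the earlier steps, chosen after their values were seen, included STAR at 1.14 and -1.20 and CYP11A1 at 0.68 and 0.27, each with a saturated pubertal spot on array 1 that makes the first value a lower bound. Of other members chosen after their values were seen, HSD3B1 was at -0.0004 and 1.76 (mean of a further probe 0.80). INSL3 was at 1.37 and -0.20 (mean of a further probe 0.03). The Leydig list fell in 12 of 13 alternatives and missed the threshold in the other, at an adjusted p of 0.403 with an intensity trend.

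**Figure D3:**
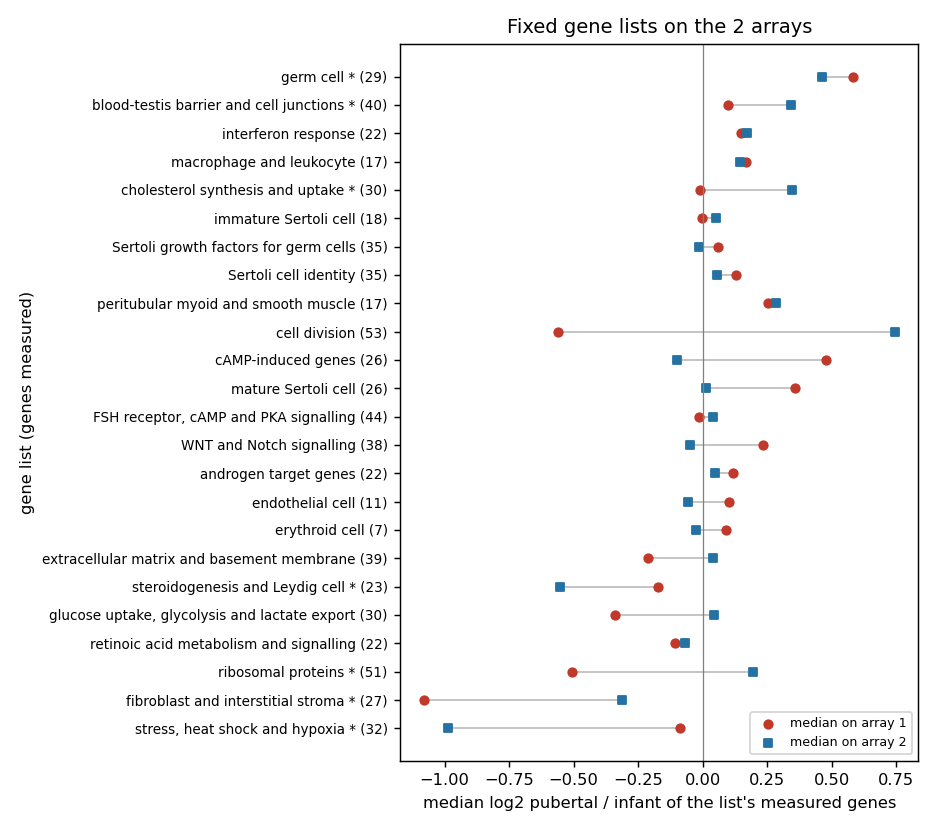
Median log2 ratio of pubertal over infant (x axis) of the measured genes of each of the 24 lists (y axis, number measured in brackets), with circles for array 1, squares for array 2 and an asterisk for lists past the camera test with the preset correlation. The germ cell medians are 0.58 and 0.46, the stromal medians -1.08 and -0.31 and the cell division medians -0.56 and 0.74.

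Stress genes fell as a group by the camera test, but stood out from random lists on array 2 only. The list lay at percentile 7.67 of random lists on array 1 and 0 on array 2, and 16 members had opposite signs. Of 32 measured, 15 were lower and 1 higher in pubertal cells on both arrays, the medians were -0.09 and -0.99, and the camera adjusted p was 1.12e-07 (adjusted p = 0.672 with an estimated correlation). The antioxidant enzyme genes TXNRD1 (-1.53 and -1.14), NQO1 (-0.93 and -2.02) and GCLM (-0.68 and -1.58) and the asparagine synthetase gene ASNS (-0.72 and -1.56) had the smallest p. HMOX1, another antioxidant gene of the list, chosen after its values were seen, was at 2.06 and -3.47. Ribosomal protein genes passed as lower (adjusted p = 0.00514, and 0.672 with an estimated correlation) with medians of -0.51 and 0.20. Of 51 measured, 12 were lower and 0 higher on both. RPS3 was at -1.05 and -0.30, RPL10 at -0.77 and -0.07, RPL22 at -0.30 and -0.32 and RPL4 at -0.40 and -0.22, and RPS3, RPL10 and RPL4 had saturated spots. Without genes that had a saturated spot, a choice made after seeing the data, 5 ribosomal genes were left and the adjusted p was 0.470. No gene of these 2 lists passed over its list alone. Stromal markers were lower beside them, at medians of -1.08 and -0.31. In the Cy5 over Cy3 direction 6 lists passed camera (0 with an estimated correlation, each at an adjusted p of 0.918), and the stromal, stress and ribosomal lists passed in both directions. Beside these, the cell division, cAMP-induced and glucose lists passed in the Cy5 over Cy3 direction alone. Without saturated genes 4 passed there, and the ribosomal list did not (adjusted p = 0.554).

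Cell division genes went opposite ways on the 2 arrays. Of 53 measured, 47 had opposite signs, with medians of -0.56 on array 1 and 0.74 on array 2 (camera adjusted p = 0.263). The members with the smallest p were CENPA (0.35 and 0.62), BIRC5 (0.10 and 1.31), PLK1 (0.13 and 0.60, mean of a further probe 0.08) and RRM1 (-0.06 and 0.89). In the Cy5 over Cy3 direction the list was lower on both arrays, with an adjusted p of 8.29e-26 (adjusted p = 0.918 with an estimated correlation).

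Markers of other testicular cells did not pass as groups under the main processing. Of 17 peritubular myoid and smooth muscle genes 6 were higher and 3 lower on both arrays (camera adjusted p = 0.247). The muscle filament genes DES (-1.07 and -1.26) and MYH11 (-1.25 and -0.63) were on the lower side, and ACTG2 (0.70 and 0.75) and TPM2 (0.95 and 0.56, saturated on 1 array) on the higher. Of 17 macrophage and leukocyte genes 7 were higher and 1 lower (adjusted p = 0.0906), with HLA-DPA1 at 1.85 and 0.30, CSF1R at 0.18 and 0.53, ITGB2 at 0.31 and 0.36 and CD163 at 2.44 and -0.36. This list passed as higher with the scanner's signals (adjusted p = 0.0066) and at an offset of 0 (adjusted p = 0.0145). Of 11 endothelial genes 3 were higher and 1 lower (adjusted p = 0.279), with VWF at a mean of 0.85 ± 0.26, SOX18 at 0.54 and 0.16 and EGFL7 at -0.10 and -0.37. The endothelial median was -0.01 although the mean of 0.14 and the test pointed up. Of 7 erythroid genes 2 were higher and 2 lower (adjusted p = 0.917), with ALAS2 at 0.27 and 0.16, HBM at -0.17 and -0.03, HBA1 at -0.02 and -0.17 and SLC4A1 at 0.09 and 0.03. ITGB2 and SLC4A1 were well above background for the infant RNA on 1 of 2 arrays.

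The 6 remaining lists did not pass in the pubertal-over-infant direction either. Of 35 Sertoli growth factors for germ cells 8 were higher and 6 lower on both arrays (adjusted p = 0.279). The Notch ligand JAG1 was at 1.56 and 1.17 and WNT3 at 1.36 and 1.09, while the growth factor IGF2 was at -1.26 and -2.75 and the chemokine CXCL12 at -1.73 and -0.57. Further probes had means of -0.63 for IGF2 and of -0.64 and -0.36 for CXCL12. Of 22 retinoic acid genes 4 were higher and 8 lower (adjusted p = 0.0906). RARRES1 (-1.56 and -1.31) passed over the list alone, RXRB was at -0.77 and -0.49 and RDH11 had a mean of 0.67 ± 0.30. Of 30 genes of glucose uptake, glycolysis and lactate export 6 were higher and 10 lower (adjusted p = 0.141), with the lactate exporter SLC16A3 at -1.64 and -1.19, PFKP at 1.05 and 1.03, SLC2A3 at -0.56 and -1.16 (mean of a further probe -0.19) and GAPDH at -1.44 and -0.30. The other 14 had opposite signs, and the glucose list's medians were -0.34 and 0.05. It passed camera in the Cy5 over Cy3 direction (adjusted p = 0.0258, and 0.918 with an estimated correlation). Of 39 extracellular matrix and basement membrane genes 11 were higher and 11 lower (adjusted p = 0.344). COL15A1 was at -2.32 and -1.16 and NID2 at -1.03 and -1.03, while COL4A4, with infant signals well above background on 1 of 2 arrays, was at 1.09 and 1.01 and MMP9 at 1.31 and 0.67. Of 38 WNT and Notch genes 11 were higher and 8 lower (adjusted p = 0.279), with the Notch target HEYL at 1.26 and 2.45 and FZD7 at -0.87 and -1.05. Of 22 interferon response genes 10 were higher and 5 lower (adjusted p = 0.118). OAS1 passed over the list alone, MX2 was at 1.66 and 0.62 (mean of a further probe 0.48), IRF7 at 1.43 and 0.46 (mean of a further probe 0.07) and IFIT2 at -0.80 and -0.47.

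In the authors' deposited table CST9L had log2 ratios of 5.66 and 5.06, PCDH17 3.16 and 3.45 and RGS5 -2.77 and -2.64. Of its 4151 probes with a value in both columns, 46.0% had the same sign in both, and the columns had an r of -0.02 across probes. Both columns of it were at least 2-fold higher in pubertal cells for 152 probes and at least 2-fold lower for 164, and 370 were at least 2-fold apart in opposite directions. Its signs matched those of the loess ratios for 98.0% of values on array 1 and 96.9% on array 2.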

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

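Spike-in controls, RNAs added to each labelling, are given here because they carried a signal in data that the comparisons of genes did not use. Averaged over the 2 arrays after turning to the pubertal-over-infant direction, 9 of 9 usable spike-ins lay below 0 after loess, with a mean log2 shift of -0.71 ± 0.09 (SD over spike-ins), from -0.79 to -0.54. On single arrays 6 of 9 lay below 0 on array 1 and 5 of 9 on array 2. These single-array counts say little about the shift, since each spike-in had a Cy5 over Cy3 ratio of its own. That ratio ran from -3.33 to 1.11 on array 1 and from -2.11 to 2.44 on array 2, with the same spike-ins lowest and highest. All 9 had a lower Cy5 over Cy3 ratio on array 1 than on array 2. The scanner's own fit of spike-in ratios had log10 intercepts of -0.16 on array 1 and 0.28 on array 2. The ratios of genes were not scaled to the spike-ins. Loess sets the bulk of each array near 0, so these ratios do not measure a difference in total RNA or in added spike-in between the cultures, and the source of the shift was not tested.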

How the results depend on the processing

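In the settings that keep both arrays, 1222 of 1229 alternative values of 103 named genes kept their direction and their side of the threshold. Aquantile scaling, the intensity trend and the separate channels leave each probe's ratio unchanged, so a direction could hardly turn there. The other 7 were the 5 in which CST9L passed and 2 near 0 that turned: the log2 ratio of SLC4A1 was -0.0407 with the scanner's signals and -0.0741 with median centring. With 1 array alone CD163 (-0.36 on array 2) and RRM1 (-0.06 on array 1) turned against their means. The count of genes past the test was 1, always CST9L, with the scanner's signals, an offset of 0, median centring, the stricter filter and an intensity trend, and 818 at an unadjusted p. The count of genes at least 2-fold apart in both arrays (138) was 483 (273 higher and 210 lower) with the scanner's signals, 299 (168 and 131) at an offset of 0 and 74 (51 and 23) with median centring. It was 562 at a threshold of 1.5-fold and 17 at 3-fold, by construction. The count of genes at least 2-fold apart in the dye direction in both arrays (156) was 379 (215 higher and 164 lower in Cy5), 263 (112 and 151) and 1530 (1521 and 9) under the first 3 of these, so the excess of lower genes turned in 2 of them, and the agreement of the 2 arrays across genes (r) was 0.0510, -0.0216 and -0.37. Median centring left medians of 0.62 on array 1 and -0.41 on array 2 over the genes tested, and the scanner's signals 0.15 and -0.12. The number of lists past the test fell from 7 to 0 with an estimated correlation and to 0 with fry (lowest adjusted p = 0.0652, for androgen targets). The setting without the offset of 50 changed nothing else, so the rise from 138 to 299 genes there came from the offset. That offset makes the ratios of dim probes smaller. Apart from this and the construction named, the cause was not tested. The germ cell, stromal, stress, barrier and cholesterol lists passed in 13 of 13 settings of the camera test with the preset correlation, the Leydig list in 12 and the ribosomal list in 10. Added after seeing the data, the list test in the Cy5 over Cy3 direction gave 6, or 0 with an estimated correlation, and leaving out the 444 genes with a saturated spot gave 6 lists and 135 genes. Without replicate 1 or without replicate 2 the number of genes at least 2-fold apart ranged from 937 to 1433, and the tests, the list tests and the correlation have no value there. The signs of the authors' deposited table matched the scanner's ratios for 99.6% of values on both arrays, against 98.0% and 96.9% for the loess ratios. The test as run pairs the 2 cultures of an array. Without the array as a replicate block, the separate channels gave 0 genes and 7 lists, so the pairing changed no call of these tests. Their 138 genes at least 2-fold apart were the same by construction, since the channels give back the same ratios. The fit with the array as a block and a dye term was not run to a result, since it leaves no residual degree of freedom within arrays. Signal over background limits the dim genes. Without the filter 32581 genes were tested and the lowest adjusted p was 0.9999. That value does not measure a limit from low signal. CST9L rose to it too, although it was well above background in both channels of both arrays.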

Other observations

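The tests of the dye effect, of dim probes and of exchanged dye labels were chosen only after the result was seen, as were the genes of the first 2 paragraphs apart from IGF2, DLK1 and GPC3, which the rule had named. Members named below as brightest were taken by intensity, outside the rule. Among the genes lower in pubertal cells on both arrays were some with known roles in fetal growth. The imprinted growth factor gene IGF2 was at -1.26 and -2.75 on arrays 1 and 2, the imprinted DLK1 at -1.32 and -1.99 and NNAT, also imprinted, at -1.29 and -2.02. IGF2BP3 (-1.39 and -1.31) and IGF2BP2 (-1.11 and -1.07), RNA-binding proteins that bind IGF2 mRNA, the chromatin gene HMGA2 (mean -1.50 ± 0.33) and GPC3 (-2.07 and -1.66) shared the direction. A further probe had a mean of -0.34 for HMGA2 and -0.63 for IGF2. None passed the limma test, and they form no list tested here.

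Some genes were more than 2-fold apart on both arrays in opposite directions. For these genes a dye effect and a difference between the cultures of the 2 pairs cannot be told apart. The retinaldehyde dehydrogenase gene ALDH1A3 was at -4.11 on array 1 and 2.38 on array 2, and the WNT inhibitor gene DKK1 at -3.45 and 2.19. HMOX1, the haem oxygenase of oxidative stress, was at 2.06 and -3.47, with its infant spots saturated on array 2, and the metallothionein gene MT2A at 1.39 and -2.42. A further MT2A probe had the same signs at 0.43 and -0.74, and probes of metallothionein genes can bind transcripts of their relatives. Other stress genes stood apart on array 2 alone: TRIB3, a kinase-like gene, was at -0.03 and -3.55 and DDIT4 at 0.02 and -2.37.

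The germ cell list was higher in pubertal cultures on both arrays. A dye effect would have given medians of opposite sign after turning. Both lay above 0, which argues against a dye effect only if the dye labels hold as given. Both also lay at percentile 100 of random lists of matched intensity. That match cannot decide on dim probes, since all 29 members were above background in the pubertal channel of both arrays but 22 in the infant channel. Under the stricter filter the 22 members left were still higher (camera adjusted p = 2.05e-09), so the rise does not rest on the others alone. A candidate explanation is more germ cell RNA in the pubertal cultures. A second list of 27 measured germ cell genes, none of them in the first, lay at percentile 100 on both arrays, with medians of 0.45 and 0.36 and 17 genes higher on both. The second list went through the same filter and was not tested under the stricter one. The intensity match thus cannot decide on dim probes for it either. Of the 29 genes of the first list 22 were above background in the infant channel of both arrays, 2 stand in other lists and 13 in the authors' deposited table; its brightest members were UCHL1 (0.60 and -0.23), AKAP4 (0.52 and 0.46), ID4 (1.01 and 0.69), POU5F1 (0.60 and -0.62) and LDHC (0.35 and 0.47), no gate that removes germ cells is stated, and expression of these genes by pubertal Sertoli cells themselves stays open as untested.

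The stromal list was lower in pubertal cultures on both arrays. It lay at or below percentile 0.11 of matched random lists on each. For the dye labels as given this argues against a dye effect as the whole source, although the list also passed in the dye direction. A lower share of stromal cell RNA in the pubertal cultures was tested on a second list of 46 measured stromal genes. Its median was -0.47 at percentile 0 on array 1 but -0.05 at percentile 39.4 on array 2, so a smaller share of stromal cells and a change of these genes within cells cannot be told apart. The brightest members of the first list, of which 26 of 27 were above background in infant cells on both arrays, 2 stand in other lists and 15 in the authors' deposited table, were SFRP1 (-0.53 and -0.30), COL1A2 (-0.69 and -0.74), DCN (-1.97 and -0.43), COL1A1 (-0.84 and -0.03) and CXCL14 (2.23 and 0.71).

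The median of the cell division list was lower in Cy5 on both arrays, with TOP2A at -1.20 and 1.11, CDC2 at -1.44 and 1.27, RRM2 at -1.62 and 1.66, CCNA2 at -1.13 and 1.42 and BUB1B at -1.24 and 1.37 as pubertal over infant, all 5 chosen after their values were seen, while the rule's CENPA (0.35 and 0.62), BIRC5 (0.10 and 1.31) and PLK1 (0.13 and 0.60) did not follow it. Against lists matched on intensity and GC content its Cy5 over Cy3 medians lay at percentile 0 on both arrays, which argues against these probe properties. Cultures that differ in dividing cells, more in the infant culture of array 1 and more in the pubertal culture of array 2, are a candidate explanation: 12 further probes of 10 of its genes, with other sequences, lay at or below percentile 0.02 on both arrays and had medians of -0.49 and -0.55. A dye bias shared by all probes of a transcript stays open as untested. Exchanged dye labels on 1 array cannot be told apart from the labels as given by the count of genes. That count was 1.13 times as high with array 2 turned the other way, at 156 against 138. It was 0.785 times as high with the scanner's signals and 0.880 times at an offset of 0. Median centring gave 20.7 times, but left the tested genes shifted towards Cy5 on both arrays.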
